A study of Drosophila melanogaster with 2 samples.

How the data were processed

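ChIP-seq of fd102C fused to GFP was analysed from peak lists of whole embryos, with 2 biological replicates in 1 group. Replicate numbers and the assembly (dm6) were taken from the labels. The labels describe both samples as input control, while their titles and assay fields name transcription factor ChIP-seq and the antibody field names fd102C. They were treated as ChIP. The age of 2 to 6 h is from the source description in the labels, while their age field gives a number of hours that no embryo could have. Whether the replicates came from separate collections is given only by the word biological in the labels. Chromatin was sonicated, per the labels.

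The deposited peak lists give, for each peak, a signal value and a summit position as the authors' caller wrote them, and the scale of that signal is not stated. The deposited −log10 q-value of each peak was used only to break ties in rank. The deposited p-value field was empty in every list. The authors called peaks on each replicate and on both replicates pooled, against a separate control that was not analysed here, per the notes deposited with the files. Each of these lists holds exactly 30000 peaks, as a limit on the number would give. The thresholded list holds the 2031 pooled peaks with the highest signal, with the same values. The aligner, the caller and the threshold are not given in the sources used here. The lists hold no read counts, so depth per sample is unknown. A list limited in number holds background as well as binding, which is why the thresholded set was the main one.

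Annotation was Ensembl release 115 for the same assembly, without transposable elements, on arms 2L, 2R, 3L, 3R, 4 and X, with 18164 genes, 13945 of them protein-coding, and 23581 TSS positions. No thresholded peak lay outside these arms. Positions were classed by summit in the order within 1 kb of a TSS, 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic. Random positions were drawn on the same arms among known bases, 1000 times for the TSS share and 100 times for the classes and the overlap of replicates. Motifs were matched on both strands within 100 bp of the summit and of a position 1000 bp away. The side of that position was drawn at random once per peak. Another draw had been looked at before, and calls of motifs near the threshold differed between draws, so the opposite side was added as an alternative after the data had been seen. GC-matched windows, 5 per peak, came from the same arm and the same 2.5-point bin of GC content, outside all pooled peaks. Gene lists (23, with 332 entries and 318 distinct genes) were fixed before the data were examined, as were the 21 motifs, the tests of the comparisons and the alternatives, except the opposite flank, the classes among summits over 1 kb from a TSS, and RYMAAYA and GTAAACA against GC-matched windows, which were added later. All entries were matched to protein-coding genes, 5 through older symbols. A gene was bound when a summit lay within 1 kb of any of its TSSs or, in the second measure, inside the gene widened by 5 kb. Lists were compared with all other protein-coding genes by two-sided Fisher's exact tests and with 10000 random lists matched on the decile of window width or widened span. All adjusted p-values are Benjamini-Hochberg over the family named. Intervals are 95% Wilson intervals over peaks or genes. Peaks and genes are not replicates, and neighbouring genes can share a peak, so these p-values do not measure variation between embryos.

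The genes named were fd102C, the genes with the nearest protein-coding TSS to the 25 highest peaks, the 10 genes with the most summits, and in each list up to 4 bound members with the highest signal and up to 2 unbound members in alphabetical order, of which some are printed. The 5 6-mers with the smallest p were named. Alternatives were each replicate alone (its 2031 highest peaks), the 1016 highest thresholded peaks, other TSS windows, protein-coding TSSs, other distances for shared summits, other motif windows, controls and consensus sequences, and other assignments of peaks to genes.

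The tests were tested on simulated data. Over 20 sets of 2031 random peaks, 1 had a TSS share with p under 0.05. None of 420 motif tests against flanks, 2 of 420 against GC-matched windows, none of 460 list tests and 3 of 120 arm tests passed. The random peaks were spread evenly along the arms, with fewer GC-matched windows and placements than in the main tests. They therefore do not show how the motif and list tests behave for peaks near TSSs or rich in A and T. With a fork head site planted in 19.9% of the windows of 1 set, the share of 40.3% that this gives was recovered. The share given and the share recovered were counted by the same matching, so their equality was fixed. The planted motif had adjusted p = 1.38e-19 by the exact McNemar test, and the planted 6-mers ranked within the first 2. A planted list of 30 genes with peaks at 15 was found with 16 bound, the other by chance. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.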

Results

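Binding of the fork head domain protein fd102C was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos of both sexes, aged 2 to 6 h by their source description. The embryos carried a transgene that joins GFP to the C-terminal end of fd102C. The samples form 1 group of 2 biological replicates, so the design holds no contrast between conditions, and no control file was analysed here. The data are 4 peak lists: 30000 peaks for each replicate, 30000 for both replicates pooled, and 2031 that passed the authors' reproducibility threshold. Read depth is unknown, since the lists give no read counts. The peak signal is the authors' own value and is used only to describe and rank peaks within a list. Coordinates are those of the dm6 assembly.

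The strongest peak of the thresholded set lay at px (plexus), a nuclear protein gene of wing vein patterning, at 2R 22514144 to 22514474, 205 bp from the transcription start site (TSS) and inside the gene. It had the highest signal in the pooled list (2068) and ranked 1 in each replicate. The next were at ph-p, a Polycomb group gene (X 2137202 to 2137505, signal 1679, 498 bp from the TSS), and 2920 bp from the nearest protein-coding TSS, that of hll (2L 14023927 to 14024252, signal 1398). The fourth lay in intergenic sequence 3913 bp from the TSS of zfh2, a zinc-finger homeodomain gene on chromosome 4 (497737 to 498069). The fifth was in an intron of sbb, which encodes a nuclear repressor protein, and the sixth in an intron of cno, which encodes an adherens junction protein. The 25 highest peaks ranked no lower than 33 in either replicate. Of these peaks, 11 lay within 1 kb of a TSS, 8 in introns and 6 in intergenic sequence. Others among them were nearest to croc, another fork head domain gene (11976 bp from its TSS), Rbfox1, Chro, CycB, Lk6 and SKIP. The peak nearest to cbt lay inside ush, and the one nearest to CG17974 lay inside cv-2, so the nearest gene need not be the one that holds the peak.

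Several long genes held many summits. Counting the gene and 5 kb on each side, CG1677 held 12, ush 10, Raf and jing 9 each, Ptp61F and sbb 8 each, RapGAP1, hth and px 7 each, and Antp 6. ush encodes a cofactor of GATA factors, hth a cofactor of Hox proteins, and Antp a Hox protein. The 10 genes span 48.4 to 132.8 kb, and counts were not corrected for length. Antp was tied with at least pros, which also held 6, and ties were ordered by symbol. CG1677 contains 13 other protein-coding genes, among them brk, and Ptp61F contains 9, among them rho.

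The question of how well the replicates matched was answered by the overlap of their strongest peaks. Of the 1000 highest peaks of replicate 1, 75.4% had a summit within 100 bp of one of the 1000 highest of replicate 2, against a mean of 0.159% for peaks placed at random on the same arms. The share was 66.9% for the 2031 highest and 53.3% for the 5000 highest, with 0.304% and 0.773% by chance. Of the thresholded peaks, 1941 (95.6%) had a summit within 100 bp in both replicates and 1 had none in either. Over those 1941 peaks the ranks of the signals in the replicates had a Spearman rho of 0.684. The authors' threshold was on reproducibility, so these 2 values do not measure the match of the replicates independently, and peaks are not independent replicates.

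Summits lay within 1 kb of a TSS more often than random positions did, and away from TSSs hardly any lay in coding exons. Of the 2031 thresholded summits, 1082 (53.3%, Wilson 95% confidence interval 51.1 to 55.4) were within 1 kb of an annotated TSS, 2.25 times the share of random positions on the same arms (23.7% ± 0.941, SD over 1000 placements). The weakest 2031 peaks of the pooled list had 30.5%. With a 500 bp window the share of thresholded summits was 44.4%, against 13.6% of random positions. With TSSs of protein-coding genes only it was 48.2%, against 20.3%. Coding exons over 1 kb from any TSS held 4 summits (0.197%), against 10.02% of random positions and 7.63% of the weakest peaks. The 4 lay in Pde1c, otp, CG10357 and klar, genes named after their values were seen. Coding exons nearer to a TSS were not counted apart. The classes exclude each other and the TSS class comes first, so an excess there lowers the others. The classes were therefore also compared among the 949 summits over 1 kb from a TSS, a comparison added after the data had been seen. Of these, 0.421% were in coding exons against 13.1% of random positions equally far from a TSS, and 2.11% in 3' UTRs against 5.53%. Introns held 62.1% against 47.1%, and intergenic sequence 33.4% against 33.0%. The median distance to the nearest TSS was 791 bp, and 360 summits (17.7%) were over 5 kb from any TSS. For the TSS share the one-sided permutation p was 0.000999, the smallest that 1000 placements can give, and the two-sided Fisher's exact test against the weakest peaks gave adjusted p = 1.68e-48. These tests are over peaks and do not measure variation between embryo collections.

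**Figure D1:**
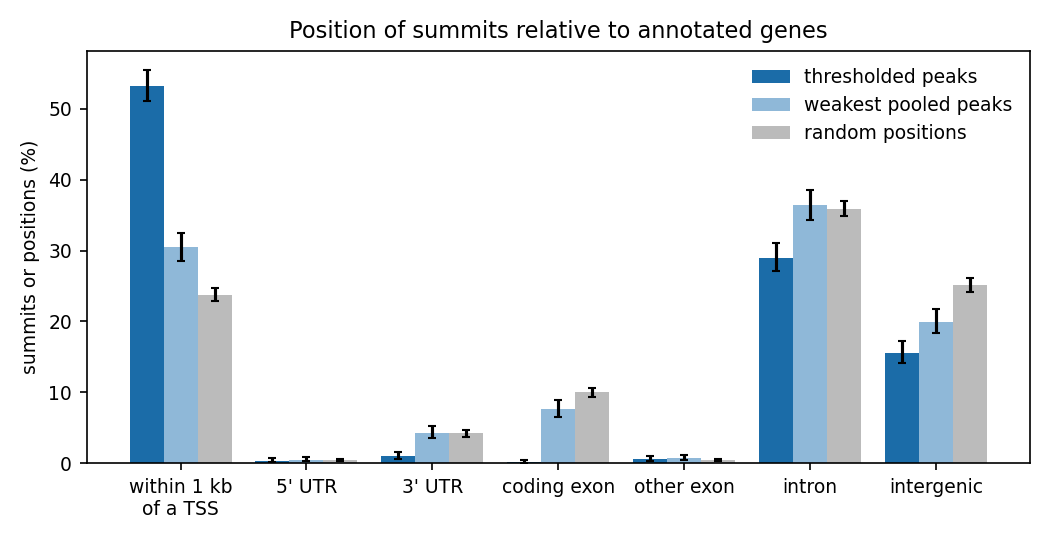
Share of summits or positions (%) in each class of the annotation, for the 2031 thresholded peaks, the weakest 2031 pooled peaks and random positions. Error bars are 95% Wilson intervals for peaks and the SD over 100 placements for random positions. Each summit is in 1 class only, and the TSS class comes first. The thresholded peaks stand at 53.3% within 1 kb of a TSS and at 0.197% in coding exons.

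Peak density on arm 2L was above, and on X below, that of the other arms pooled. 2L had 410 peaks, 17.4 per Mb, or 1.18 times the density of the other arms (exact binomial test, adjusted p = 0.00731 over 6 arms), and X had 299, 12.7 per Mb, or 0.810 times (adjusted p = 0.00385). Chromosome 4, which carries fd102C and is largely heterochromatic, had 15 peaks, 11.3 per Mb, or 0.740 times, and did not pass the exact test (adjusted p = 0.567). Arms 2R, 3L and 3R did not pass the exact test either (adjusted p = 0.567 for each). Densities are per Mb of sequence. They were not corrected for the number of TSSs on each arm or for the copies of X in embryos of both sexes.

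No thresholded peak lay within the tagged gene itself. fd102C lies on the minus strand of chromosome 4 at 836986 to 844529. The only thresholded peak within 5 kb, at 834079 to 834438, was 2727 bp beyond its 3' end and 10270 bp from its TSS. That peak lay 134 bp from a TSS of Sox102F, a neighbouring SOX-domain gene, and had no RTAAAYA site within 100 bp. It ranked 1396 in the thresholded set, 2079 in replicate 1 and 1193 in replicate 2, so it is not among the 2031 highest peaks of replicate 1.

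Sequences of the fork head type were more frequent at summits than beside them. The consensus RTAAAYA, which many fork head domain proteins bind, was present within 100 bp of 43.1% of the summits (95% interval 40.9 to 45.2) and in 26.4% of windows 1000 bp away (exact two-sided McNemar test, adjusted p = 3.28e-27 over 21 motifs). Summit windows were richer in A and T than the flanks (38.0% against 42.4% GC). Against random windows of the same GC content the consensus was found in 30.3%, a difference of 12.7 points in place of 16.7 (Fisher's exact test, adjusted p = 1.09e-26). Of the other 20 motifs, 4 were also more frequent at summits against both controls, and all 4 are shown here. By the exact McNemar test, CTCF sites were at 4.83% of summits against 1.87% of flanks (adjusted p = 1.22e-06), DREF sites at 2.90% against 0.394% (adjusted p = 1.07e-09), M1BP sites at 1.53% against 0.394% (adjusted p = 0.00154) and BEAF-32 sites at 27.2% against 22.4% (adjusted p = 0.00176). In the 1016 highest peaks M1BP (adjusted p = 0.750) and BEAF-32 (adjusted p = 0.547) did not pass the exact test. The BEAF-32 consensus CGATA lies inside the DREF consensus TATCGATA, so each DREF site counts for both. Neither control was matched on distance to a TSS. Within 1 kb of a TSS lay 2083 of the 10155 GC-matched windows, against 1082 of the 2031 summits. The excess of these 4 motifs was therefore not told apart from the position of peaks near TSSs.

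The other 16 motifs did not pass the exact test against the flanks, among them those of the early embryonic activator Zelda (6.99% against 5.81%, adjusted p = 0.255) and of GAGA factor (4.97% against 3.84%, adjusted p = 0.215). For several of them the call depended on the control, the window or the replicate. Zelda (adjusted p = 0.000409), GAGA factor (adjusted p = 9.54e-11) and GATA factor (adjusted p = 4.32e-05) sites were more frequent at summits than in GC-matched windows by Fisher's exact test, while Bicoid, TCF and TEAD sites were less frequent. Homeodomain sites were at 14.0% of summits and 15.4% of GC-matched windows (Fisher's exact test, adjusted p = 0.146), so their difference turned from 2.12 points against the flanks to -1.45 points. Without replicate 1 GATA factor (adjusted p = 0.00930) and homeodomain sites (adjusted p = 0.0267) passed the exact test against the flanks. With the flank on the opposite side of each peak, the exact test was passed by GATA factor (adjusted p = 0.00495) and homeodomain sites (adjusted p = 0.0110) as higher and by TEAD sites as lower (adjusted p = 0.0393). With 250 bp on each side of the summit and of the flank position, GAGA factor sites exceeded the flanks by 7.53 points (exact McNemar test, adjusted p = 3.46e-13) and Zelda sites were also more frequent (16.4% of summits, adjusted p = 0.0240), while Bicoid sites were less frequent (adjusted p = 0.00228).

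**Figure D2:**
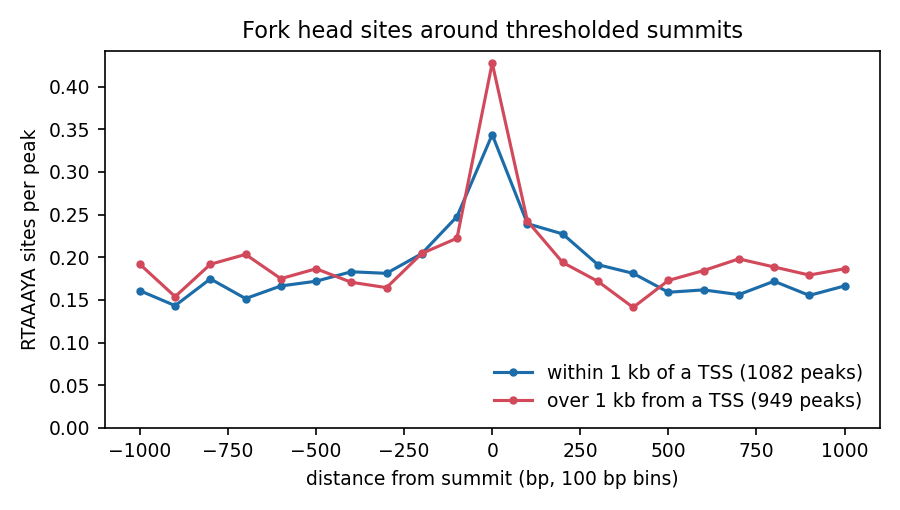
RTAAAYA sites per peak in 100 bp bins from 1000 bp before to 1000 bp after the summit, for peaks within and over 1 kb from a TSS. The central bin holds 0.344 sites per peak near TSSs and 0.428 away from them, and the outermost bins hold 0.161 to 0.192.

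Of all 2080 6-mers, 279 were more frequent at summits than in the flanks and 494 less frequent. The 5 with the smallest p were AAATAT (50.8% of summits against 30.7%), TAAATA (45.6% against 27.2%), AATATT (30.1% against 16.3%), AAATAA (50.3% against 34.2%) and ACACTG (18.3% against 7.48%). All 5 also passed against GC-matched windows, where ACACTG had the smallest p of all 6-mers (7.04% of those windows, Fisher's exact test, adjusted p = 1.03e-46). Against GC-matched windows 279 were again higher, but 316 were lower in place of 494, and only 125 6-mers were higher against both controls.

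Ribosomal protein genes were the list most often bound at the promoter. A summit lay within 1 kb of a TSS for 23 of 34 of them (67.6%), among them RpL7, RpS27, RpL14 and RpS4, while RpL15 and RpL21 had none. Over all 13945 protein-coding genes the share was 9.08%. Of 17 Notch pathway and Enhancer of split genes, which act in lateral inhibition, 9 were bound, with the highest signals at E(spl)m7-HLH, E(spl)m2-BFM, E(spl)mdelta-HLH and E(spl)m3-HLH, and Delta was not. Of 16 EGF and FGF receptor pathway genes 7 were bound, among them stumps, aos, spi and edl, and Egfr and btl were not. Of 10 pair-rule genes, which divide the embryo into segments, 5 were bound (hry, odd, opa, ftz and slp1, the last named after its value was seen), and eve and prd were not. Adjusted p over the 23 lists was 2.22e-15, 5.81e-05, 0.00210 and 0.00601 for these 4 lists, and 0.00230, 0.00230, 0.0230 and 0.0199 against random lists matched on the width of the TSS windows. Those random lists were not matched on clustering of genes, though the 9 bound Notch pathway genes had 10 distinct peaks. For pair-rule genes the call by Fisher's exact test was lost without replicate 1 (3 of 10 bound, adjusted p = 0.241) and in the 1016 highest peaks (adjusted p = 0.232).

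The other 19 lists did not pass the test, though tracheal genes did so with a TSS window of 500 bp (4 of 12 bound, Fisher's exact test, adjusted p = 0.0482). Among fork head domain genes 4 of 17 were bound, at fkh, FoxK, CHES-1-like and slp1 (Fisher's exact test, adjusted p = 0.158). Neuroectoderm genes had 4 of 17 bound (pros, brk, D and vnd) and dorsal ectoderm genes 4 of 15 (Doc1, pnr, ush and peb). Tracheal genes had 4 of 12 bound (bnl, rho, trh and rib) and mesoderm genes 3 of 16 (tin, org-1 and stumps). The list named early zygotic cellularization and sex determination, which also holds bcd and zld, had 3 of 10 bound (bcd, zld and Sxl). Endoderm genes had 2 of 8 bound (fkh and bowl). Only 1 member was bound in the segment polarity (nkd), Hox (lab), haemocyte (ush), neuronal (elav) and photoreceptor (Rh5) lists. No member was bound among 11 gap genes, 10 germ line, 15 muscle, 21 odorant receptor, 14 chorion, 10 accessory gland and 14 serum, yolk and glue protein genes. With lists of this size a count of 0 does not pass the test against a background of 9.08%.

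**Figure D3:**
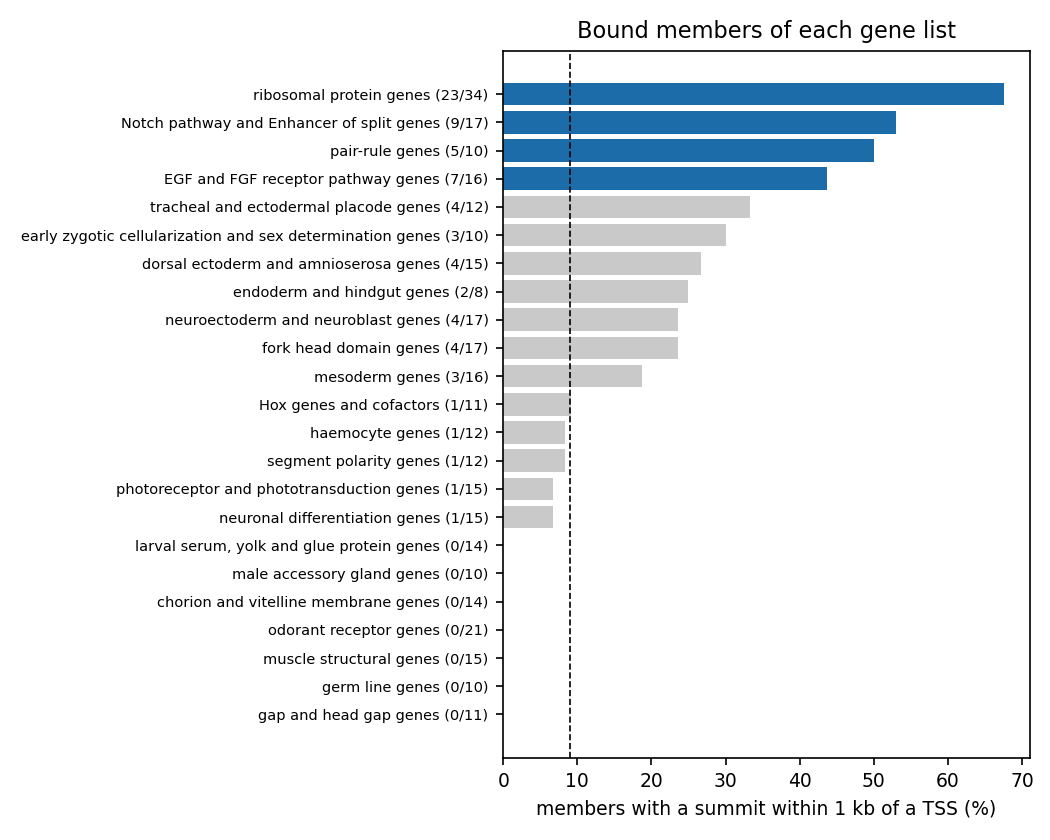
Members of each of the 23 gene lists with a thresholded summit within 1 kb of a TSS (%), with counts beside the names. Blue bars passed Fisher's exact test after adjustment and grey bars did not, and the dashed line marks 9.08%, the share over all protein-coding genes. Ribosomal protein genes stand highest at 67.6%.

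When the whole gene and 5 kb on each side were counted, 15 of 17 Notch pathway genes and 24 of 34 ribosomal protein genes held a summit, against 23.9% of all protein-coding genes. The Enhancer of split genes lie close together, so neighbours can share a peak. By Fisher's exact test 9 lists passed. The other 7 were pair-rule (7 of 10), Hox (8 of 11), fork head domain (10 of 17), dorsal ectoderm (8 of 15), neuroectoderm (9 of 17), EGF and FGF receptor pathway (10 of 16) and endoderm genes (6 of 8). Against lists matched on the length of the gene with its surroundings only the Notch and ribosomal protein lists passed (permutation test, adjusted p = 0.00230 for both). Before adjustment p was 0.0002 for each, the smallest that the random lists can give. The random lists were not matched on clustering of genes. The p for the Notch list therefore treats neighbours that can share a peak as independent. The 7 lists that did not pass had adjusted p from 0.0521 for pair-rule to 0.194 for dorsal ectoderm genes in that permutation test. For pair-rule genes the matched lists had a mean of 2.55 bound, against 7, and for dorsal ectoderm genes 4.40, against 8. Calls by Fisher's exact test also changed in the alternatives. Without replicate 1 they were lost for pair-rule (6 of 10 bound, exact test, adjusted p = 0.0553), dorsal ectoderm (7 of 15, adjusted p = 0.127) and endoderm genes (5 of 8, adjusted p = 0.0648), and for neuroectoderm genes with 9 of 17 bound in both cases (adjusted p = 0.0553). Without replicate 2 they were lost for fork head domain (7 of 17, exact test, adjusted p = 0.284), dorsal ectoderm (7 of 15, adjusted p = 0.129) and endoderm genes (5 of 8, adjusted p = 0.0642). Tracheal genes, with 6 of 12 bound in the thresholded set (exact test, adjusted p = 0.0856), passed with 8 of 12 without replicate 1 (adjusted p = 0.0103) and 7 of 12 without replicate 2 (adjusted p = 0.0358). In the 1016 highest peaks the call was lost for neuroectoderm (3 of 17, exact test, adjusted p = 0.620), endoderm (3 of 8, adjusted p = 0.179) and fork head domain genes (6 of 17, adjusted p = 0.0521), and gained for mesoderm genes (6 of 16, adjusted p = 0.0433). With 2 kb on each side it was lost for neuroectoderm genes (6 of 17, exact test, adjusted p = 0.0821). When each peak was assigned to the nearest TSS, calls were gained by exact test for tracheal (8 of 12, adjusted p = 1.98e-05), gap (6 of 11, adjusted p = 0.000924), mesoderm (6 of 16, adjusted p = 0.00837) and segment polarity genes (5 of 12, adjusted p = 0.00977).

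Strong peaks carried the fork head consensus more often than weak ones. It was present in 47.7% of the 507 peaks in the highest quartile of signal and in 38.2% of the 508 in the lowest (two-sided Fisher's exact test, p = 0.00234). From replicate 1 alone the difference was 6.20 points (exact p = 0.0508). The TSS share was 49.9% in the highest and 54.1% in the lowest quartile (exact p = 0.187), and with a 500 bp window the difference of the highest minus the lowest quartile was -8.58 points (exact p = 0.00645).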

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

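The 2031 pooled peaks ranked next below the threshold were examined as data outside the main set. They are not unused data. The peaks of single replicates above can lie at the same places, and GC-matched windows were drawn outside all pooled peaks. These next 2031 peaks carried RTAAAYA at 38.9% of summits (95% interval 36.8 to 41.1) against 25.9% of flanks. The difference was 13.0 points (exact McNemar p = 1.79e-18), compared with 16.7 points in the thresholded set. Of them 1738 (85.6%) had a summit within 100 bp in both replicates, and 57.9% lay within 1 kb of a TSS. The weakest 2031 pooled peaks had a difference of 0.345 points (exact p = 0.831), and 18 of them (0.886%) had a summit in both replicates. Each replicate list ends at 30000 peaks, so a weak pooled peak can be missing from it for that reason alone. The shares with a summit in both replicates therefore do not measure how well weak peaks reproduce.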

How the results depend on the processing

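The main results were kept in 38 of the 44 combinations of result and alternative. Counts and shared peaks apart, a result that passed in the main setting was kept with the same direction and side of the threshold. None of these reversed. A result that did not pass was kept when the alternative did not pass either, whatever its direction. None of those passed in the opposite direction. Counts were taken as kept within 1.5 times, and the share of peaks shared between replicates within the 95% interval of its main value. These had no direction that could reverse. A kept count can hide a change of members, as the 279 6-mers higher against each control had only 125 in common. The share of peaks within 1 kb of a TSS stayed above random placement throughout, from 44.4% with a 500 bp window to 64.5% with 2 kb. The fork head consensus exceeded its control by 5.49 to 20.1 points over all alternatives. The lowest differences, 5.49 and 5.61 points, were those of GTAAACA alone, which was at 9.90% of summits against 43.1% for RTAAAYA. Points do not rank enrichment between consensus sequences of such unlike frequency. The alternatives with another consensus against GC-matched windows and with the opposite flank were chosen after seeing the data. The share of the 2031 highest peaks shared between replicates moved to 55.5% with summits within 50 bp and to 71.0% within 250 bp. The number of peaks near fd102C was 0 in the 1016 highest peaks and ranged from 0 to 1 over the single replicates. The highest quartile of signal had a lower TSS share than the lowest with a 500 bp window, by a difference of -8.58 points that was past the threshold. Its excess of the fork head consensus ranged from 6.20 to 7.57 points over the single replicates, and was not past the threshold from replicate 1 alone. The cause of these changes was not tested. Lists passing in the gene neighbourhood numbered 6 to 13 against 9. Among single motifs, arms and lists, 348 values kept their call, 22 gained one and 15 lost one. The unknown depth limits how weak peaks can be read.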

Other observations

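The explanations in this part were devised after the patterns had been seen. The comparisons on TSS width and on GC content had been planned, but were chosen as tests of an explanation only after their results were seen, and the comparison of translation factor with ribosomal protein genes was not planned. The design has 1 group, so no explanation by a difference between groups was tested.

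Other genes of the translation machinery were also bound at their promoters. Of 19 translation factor genes 7 were bound (36.8%, Fisher's exact test, adjusted p = 0.00284 over 3 lists), namely eEF1gamma, with the highest signal (420.6), eIF6, eIF3a, eEF2, eIF3c, eEF1alpha1 and eIF2beta. Of 25 respiratory chain and ATP synthase genes 5 were bound (blw, COX5A, ATPsynbeta, COX6B and ATPsynC, exact test, adjusted p = 0.106), and of 31 proteasome subunit genes only Rpn3 (adjusted p = 0.359). All were named after their values were seen.

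The binding at ribosomal protein promoters could come from promoters of constitutively used genes being recovered in general. The 3 other lists together had 13 of 75 genes bound (17.3%). This was fewer than for ribosomal protein genes (Fisher's exact test, p = 4.97e-07) and more than for the remaining genes (Fisher's exact test, p = 0.0234). It argues against constitutive use by itself as the whole cause. Translation factor genes alone were also below ribosomal protein genes (exact p = 0.0439). The lists were not matched on promoter activity, which peak lists do not give, so recovery that rises with activity stays open. The width of TSS windows did not account for the binding at ribosomal protein promoters (permutation test, adjusted p = 0.00230 against matched lists). Only 5 of the 23 peaks (21.7%, Wilson interval 9.66 to 41.9), at RpS18, RpL18, RpL11, RpL5 and RpL10, had an RTAAAYA site. The share was 42.3% for other peaks near TSSs (Fisher's exact test, p = 0.0549). For all thresholded peaks, the flanks had 26.4% and the GC-matched windows 30.3%, both within the interval of 9.66 to 41.9. Controls for the 23 peaks alone were not made, so an excess at these promoters was not measured. Most of these peaks lacked the site, which argues against RTAAAYA near the summit as what brings the protein to all of them. Whether it does so at some stays open, because the peaks are too few. Other fork head sequences were not tested there.

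The fork head sites at summits could reflect base composition. At equal GC content the summits still exceeded the control by 12.7 points, which argues against GC content as the whole cause. Of the 210 arrangements of the letters of RTAAAYA, 1 (0.476%), the consensus itself, had a ratio of summit to GC-matched share as large (1.42, against a median of 1.08). The next was RYAAATA with 1.41, which has RTAAATA in common with the consensus, and then AYAARTA with 1.34. This argues against the letters without their order as the whole cause. Other sequences of A and T were also more frequent at equal GC content, such as AAATAT (50.8% against 39.2%), and what part they have stays open.

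The 6-mer ACACTG, not among the fixed motifs, could be a sequence of promoters in general. It was at 18.0% of peaks over 1 kb from a TSS and at 7.12% of GC-matched windows that far away (Fisher's exact test, p = 5.65e-25), which promoters near annotated TSSs do not explain. It was also at 14.1% of TSSs of protein-coding genes without a peak, and unannotated promoters were not tested. Leaving out windows with CACACACA kept the difference (18.1% against 6.93%, exact p = 2.77e-47), which argues against runs of CA repeats. Peaks with ACACTG carried RTAAAYA in 40.3% and those without in 43.7% (exact p = 0.247). The 6-mers with the next smallest p against GC-matched windows, ACAGTG, CACTGA and CAGTGC, also hold CACTG on one strand. They were named after their values were seen. ACACTG is thus part of a group of overlapping sequences. It also shares ACACT with the end of the M1BP consensus GGTCACACT, which was at 1.53% of summits. Which protein binds ACACTG stays open.

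Within 5 kb of fd102C the unthresholded lists held 16 summits in replicate 1 and 10 in replicate 2. As many were found in 0.540% and 23.6% of other windows of 17.5 kb on chromosome 4, and in 0.643% and 8.22% of windows over all arms. The pooled list held 15 summits there, a number reached in 1.77% of the windows on chromosome 4 and 1.13% of those over all arms. The difference between the replicates was not tested. The embryos carried a transgene holding fd102C, and the lists do not give how many copies of this region were present.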
